A study of Mus musculus with 4 samples.

How the data were processed

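RNA sequencing of subcutaneous mouse tumors was deposited for 2 groups, grown from R728T1 cells with a luciferase control shRNA (shLuc) or with knockdown of Taz (shTaz). The labels list 2 samples for each group, 4 in all, and give no further detail on how many animals they came from. Per the labels' protocols, RNA was extracted from frozen tumors with Trizol and libraries were made by standard Illumina protocols. The series' design text names an Illumina HiSeq instrument. Per the submitters' processing notes, Trim Galore and TopHat were used and the genome build was mm10. Neither tool's version is given in the sources used here, nor are the FPKM program, the gene annotation, the read length or the strand setting.

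The authors deposited FPKM values (fragments scaled to transcript length and to the mapped total) for 15424 genes, in 1 column per group. The heading of each column matches a label that both samples of that group carry, so each column was read as the authors' value for the group. Whether it is a mean, a joint estimate or a single library is not stated. No value per sample was used, so there is no spread between replicates, and no SD, test or p-value can be given. Genes at 0 in both columns are not listed. In the names of 23 genes a spreadsheet had turned the symbol into a date, and 638 genes have no Entrez identifier. FPKM divides by transcript length and library total. It corrects neither for GC content nor for a few very abundant RNAs, and its values move when such RNAs take up more of the reads.

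Depth is unknown. Low FPKM values multiplied by transcript length were searched for steps of whole reads. The best step placed 26.6% of 688 low shLuc values and 25.5% of 557 low shTaz values within 0.1 of a whole step. By chance 20% would do so for a single step set beforehand, and more for the best of many steps. Only a limited range of steps was searched, and no read number was recovered. No counting interval is given for any value.

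The plan fixed before the data were examined was a limma test on log2(FPKM + 1), with camera set tests on the gene lists. For a table with only 1 column per group, the plan was to run no test and to name genes by size alone, and that was done. Placing list medians among random lists, described below, was not part of that plan and took the place of camera. The difference of a gene is log2((shTaz FPKM + 1) / (shLuc FPKM + 1)), which understates the change of genes near or under 1 FPKM. It was computed from the deposited values without further scaling for the 11650 genes with a mean of at least 1 FPKM. A difference of 1 on this log2 scale is called 2-fold. No fold is given where a gene is listed at 0 in either column.

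The 21 gene lists were also fixed before the data were examined. They hold 324 genes, of which 285 were found among the listed genes under their current or an older symbol. For a list with at least 3 measured members, the median difference was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean FPKM. The resulting percentile describes these 2 columns and is not a p-value. Percentiles under 2.5 or over 97.5 are called outside the range of random lists. About 1 of the 20 lists with enough members would lie outside by chance if genes varied independently. Members of a list can vary together between any 2 tumors, so more lists may lie outside without an effect of the knockdown. The smallest and largest percentiles that the draw can give are 0.0049995 and 99.995.

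Genes to be named were Wwtr1, Tafazzin (listed under its older symbol Taz) and Yap1, the 10 genes with the largest positive and the 10 with the largest negative difference, and up to 4 members of each list with 2-fold differences, or else the 2 members that differed most. Predicted genes, pseudogenes and clone names were left out. Because this took up many small RNAs and near-identical gene copies, a second rule was added after the values were seen. It takes protein-coding genes with a mean of at least 5 FPKM, over 0.5 FPKM in both columns and a transcript of at least 500 bases, outside the histone, ribosomal protein and a few near-identical families. Other members of the lists that are named were chosen after their values were seen.

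Transcript length and GC content came from the longest transcript of each gene in the GENCODE M21 annotation of mm10, which gave both for 94.9% of the 11650 genes. Positions are from the same annotation, counted from 1. Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-ratio scaling and quantile normalization. Alternatives chosen after seeing the data were removal of the length trend, of the GC trend or of both (lowess with a span of 0.3), genes above 0 in both columns, protein-coding genes, and random lists matched on mean FPKM together with length or GC content in 10 bins each. A further 7 lists were also chosen after seeing the data. The percentile procedure was tested on simulated differences, drawn independently for 11650 genes, with lists of 15. Of 100 unchanged lists 5 lay outside the range, and of 100 lists lowered by 1 on the log2 scale 99 did. The first number follows from how the range is set. Smaller lists, smaller shifts and matching on GC content were not simulated. In another simulation, short genes differed only through a length trend that was steeper than the one in these data. There 97 of 100 lists lay outside with matching on expression alone, and 7 of 100 with matching on expression and length. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.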

Results

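The transcriptome was measured in tumors that grew under the skin of nude mice, which lack mature T cells, after transplantation of R728T1 cells. The labels describe these cells as non-SMCs from a mouse model based on Rb and P53, without spelling the term out, and give the cell type as small cell lung cancer. Control tumors carried an shRNA against luciferase (shLuc) and the others an shRNA against Taz (shTaz). The labels list 2 samples per group, and the deposited FPKM table holds 1 column per group. There are no replicate values, so none of the differences has a replicate check. The FPKM values summed to 501728 in the shLuc column and 427921 in the shTaz column over 15424 genes, and the sequencing depth is unknown. Across the 13749 genes above 0 in both columns, the log2 values had a Pearson correlation of 0.939. Genes are not independent replicates.

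The comparison asks how tumors with Taz knockdown differ from control tumors. The name Taz fits a pair of genes, and both were lower in the shTaz column. Wwtr1, which encodes TAZ, the transcriptional coactivator of the Hippo pathway, was at 23.4 FPKM in the shLuc column and 15.1 FPKM in the shTaz column, or 64.5% of the control value. Taz in the deposited table is the older symbol of Tafazzin, a mitochondrial enzyme that remodels cardiolipin, and it was at 13.7 and 9.50 FPKM. Yap1, which encodes the related coactivator YAP, was higher, at 8.59 and 12.0 FPKM.

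On the log2 scale Wwtr1 differed by -0.60 and 9.36% of the 11650 genes lay lower, while Taz differed by -0.48 and Yap1 by 0.44. With the trends of GC content and length removed, the Wwtr1 difference was -1.09, that of Taz -0.74 and that of Yap1 -0.01. Yap1 was then nearly equal between the columns. Wwtr1 (Entrez 97064) lies on chromosome 3 from 57455649 to 57575910 on the minus strand of mm10, Taz (Entrez 66826) on chromosome X from 74281912 to 74290151 on the plus strand, and Yap1 (Entrez 22601) on chromosome 9 from 7931999 to 8004596 on the minus strand. The labels do not state the sequence that the shRNA targets.

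Among the protein-coding genes taken by the second rule, the lower end held Nov (22.0 and 1.27 FPKM in the shLuc and shTaz columns), a matricellular protein gene, Sfrp2 (17.9 and 1.05 FPKM), a secreted Wnt modulator gene, and Dpt (18.4 and 1.16 FPKM), which encodes dermatopontin. Several of these lower genes, such as Igfbp6, were near the rule's floor of 0.5 FPKM in the shTaz column. Tpsab1, a mast cell tryptase gene, was at 17.3 and 0.895 FPKM, and Igfbp6 at 12.6 and 0.561 FPKM. Cilp2, Agt, Apod, Fxyd6 and Twist2 completed these 10, with log2 differences from -3.14 to -2.55. At the upper end, S100a9, a calcium-binding protein gene of neutrophils, was at 0.810 and 29.2 FPKM, and Amot, which encodes angiomotin, at 2.36 and 13.1 FPKM. Cxcl5, a neutrophil chemokine gene, was at 1.66 and 8.80 FPKM, and Pparg at 1.95 and 8.33 FPKM. Acyp2, Zfp825, Isoc1, Nusap1, Gcnt1 and Cenpp completed these 10, with log2 differences from 1.59 to 1.99.

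In all, 840 genes (7.21% of 11650) differed 2-fold or more, 461 of them higher and 379 lower in the shTaz column. The median of all genes was 0.12, and 0.03 over the genes with a mean of at least 5 FPKM. It is not the expected median of each list, because the difference varied with expression. Random lists matched on expression had a typical median of -0.13 for the macrophage markers and 0.20 for the interferon-stimulated genes. The percentiles below take this into account, and counts of members above or below the median of all genes do not. The split moved with the scaling. It was 310 higher and 493 lower after median-ratio scaling, 294 and 452 after quantile normalization, 293 and 392 with the length trend removed, 166 and 350 with the GC trend removed, and 184 and 308 with both removed.

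The genes taken by size alone were less certain. The small RNA genes Snord71, Snora3, Snora34, Snora43, Snora81, Snora23 and Snora74a were listed at 0 in the shTaz column and at 11.1 to 845 FPKM in the shLuc column, whereas Mir1954 and Snora64 were listed at 0 in the shLuc column and at 480 and 107 FPKM in the shTaz column. FPKM is unstable for such short transcripts. Of the 12 genes listed at 0 in one column and with at least 10 FPKM in the other, 9 had transcripts under 200 bases. Hist1h4n, Hist1h3e, Rpl26 and Rnaset2a belong to families with near-identical copies and are uncertain. The rest were S100a8, S100a9, Acta1, Krt71 and Sprr1a among the higher genes, and Clec3b (15.7 and 0.335 FPKM) and Tnn (12.9 and 0.235 FPKM) among the lower. Clec3b encodes tetranectin and Tnn the matrix protein tenascin N.

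**Figure D1:**
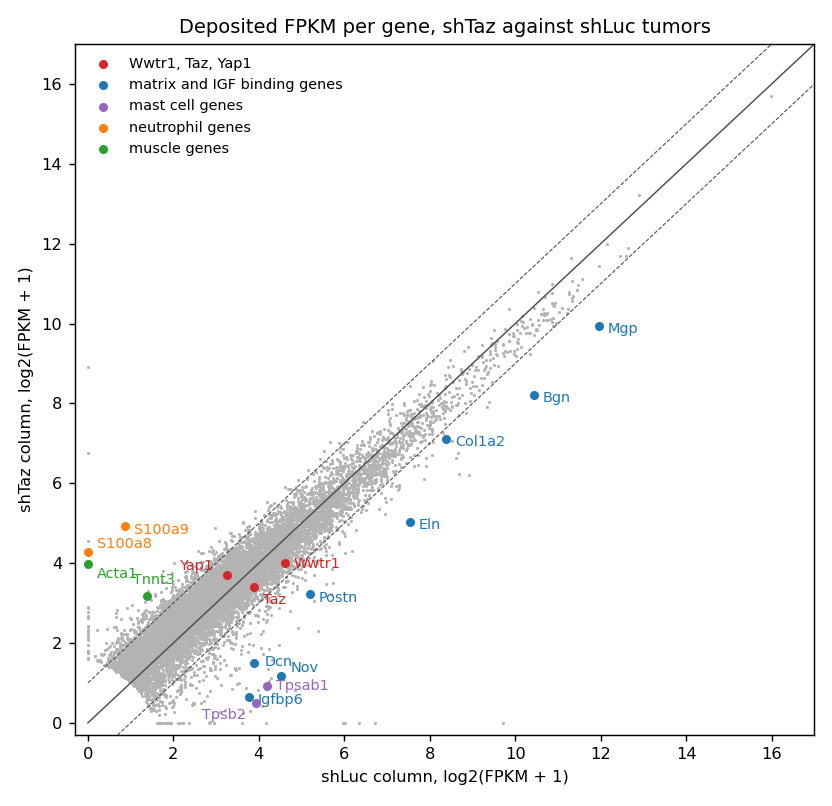
Each grey point is 1 of the 11650 genes with a mean of at least 1 FPKM, placed by log2(FPKM + 1) in the shLuc column (x axis) and in the shTaz column (y axis); the solid line marks equal values, the dashed lines a difference of 1 on the log2 scale, and colors mark named genes. The matrix and insulin-like growth factor binding genes marked in color, among them the matrix genes Bgn (1388 and 294 FPKM) and Mgp (3956 and 985 FPKM), lie under the lower dashed line. Of the genes of these kinds that are not marked, some, such as Fmod and Igfbp2, also lie under it. Others, such as Col3a1 and Htra1, do not. Wwtr1 lies between the equality line and the lower dashed line.

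The difference followed the base composition of transcripts. AT-rich transcripts were higher and GC-rich transcripts lower in the shTaz column. The genes were divided into 10 groups of equal size by GC content. In the group of genes with the lowest GC content (31.2% to 41.8%) the median difference was 0.56, and 140 of 1106 genes were 2-fold higher against 12 lower. In the group with the highest GC content (58.1% to 75.9%) the median was -0.38, and 8 of 1105 genes were 2-fold higher against 106 lower. Across genes the Spearman correlation of the difference was -0.56 with GC content and 0.30 with transcript length. Each list below was therefore also set against random lists matched on GC content or on length, and after removal of both trends. These comparisons were chosen after the data were seen and are given where they change the call.

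**Figure D2:**
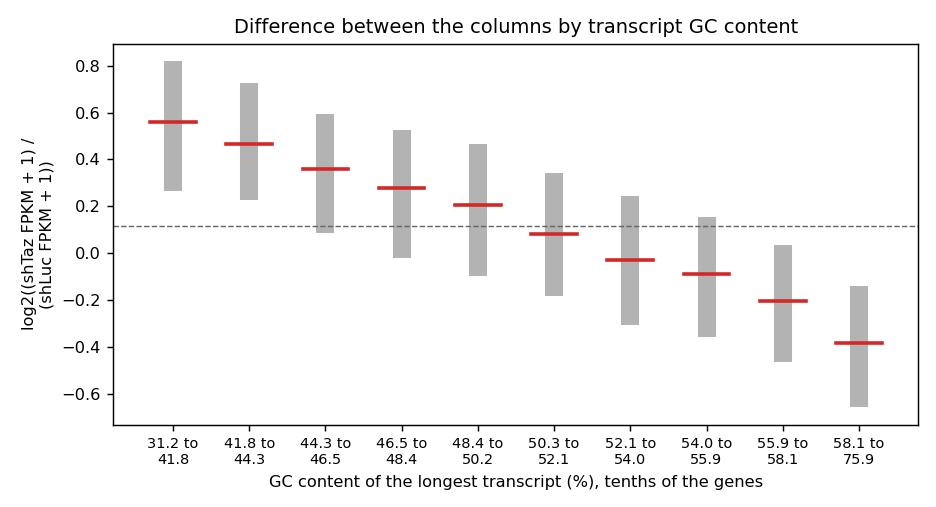
The genes were divided into 10 equal groups by GC content of the longest transcript (x axis, in percent); red bars are the median log2 difference between the shTaz and shLuc columns (y axis), grey bars run from the 25th to the 75th percentile of genes, and the dashed line is the median of all genes, 0.12. The medians run from 0.56 in the group with the lowest GC content to -0.38 in the group with the highest.

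Fibroblast and matrix genes were lower in the shTaz column. Of 14 measured members 5 were 2-fold lower and none 2-fold higher, and 12 lay below the median of all genes. Dcn, the proteoglycan decorin, was at 13.8 and 1.85 FPKM in the shLuc and shTaz columns, Postn, the matricellular protein periostin, at 35.5 and 8.29 FPKM, Fbln1 at 10.9 and 2.52 FPKM, and Col1a2, a chain of type I collagen, at 334 and 138 FPKM. Col3a1 was nearly equal (372 and 371 FPKM), and Col6a3 and Pdgfra were higher, Pdgfra at 8.75 and 13.5 FPKM. The list median was -0.64, at the 0.015 percentile of random lists matched on expression, and it lay under 2.5 in each of the 12 alternatives run.

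YAP/TAZ target genes showed no common direction. Of 20 measured members only Cyr61 (also called Ccn1) was 2-fold lower, at 155 and 60.1 FPKM, followed by Ankrd1 at 8.83 and 4.17 FPKM. Ctgf, or Ccn2, was at 27.8 and 23.4 FPKM, while Axl (42.4 and 59.4 FPKM) and Asap1 (15.4 and 26.3 FPKM) were higher. The list median was -0.08, at the 13.7 percentile. It lay outside the range of random lists with quantile normalization (2.40), with the length trend removed (2.08) and with matching on length (1.75), and in the middle with the GC trend removed (49.1). The settings that use length or GC content covered 19 members.

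Among Hippo pathway components, 3 of 19 measured members were 2-fold higher and none 2-fold lower. They were Amot, the kinase adaptor gene Mob1a (2.96 and 7.56 FPKM) and the kinase gene Stk3 (5.07 and 11.3 FPKM). The list median was 0.42, at the 97.6 percentile. This call was borderline and held in only 1 of the 12 alternatives, median-ratio scaling (97.515). It was lost with a pseudocount of 0.1 (97.2), no filter (89.2), a mean of at least 5 FPKM (88.7), quantile normalization (97.2), genes above 0 in both columns (97.2) and protein-coding genes (96.7). It was also lost with matching on GC content (89.2) or length (90.5), and with the length trend (76.8), the GC trend (68.7) or both (69.6) removed. The cardiolipin pathway, included because of the name Taz, had a median of 0.00 over 8 members, at the 25.7 percentile. Its largest differences were those of Lclat1 (3.36 and 5.54 FPKM) and Taz itself.

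Neuroendocrine genes were few and mostly lower. Of 25 genes in the list 6 reached a mean of 1 FPKM. Uchl1, a neuronal ubiquitin hydrolase, was at 10.1 and 1.51 FPKM in the shLuc and shTaz columns, and the lung transcription factor gene Nkx2-1 at 2.51 and 0.939 FPKM, while Ncam1 was at 39.8 and 43.8 FPKM. The list median was -0.48, at the 0.775 percentile, and it lay inside the range with matching on GC content (6.24), with the GC trend removed (4.69) and with a mean of at least 5 FPKM (5.13).

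Mesenchymal and non-neuroendocrine genes showed no common direction. Of 18 members only Twist2, a mesenchymal transcription factor gene, was 2-fold different, at 10.6 and 0.983 FPKM, and the abundant Lgals1 was at 2607 and 1641 FPKM. Fn1 (476 and 679 FPKM) and Zeb1 (5.41 and 8.34 FPKM) were higher. The median was -0.01, at the 63.8 percentile, and its sign turned with quantile normalization (0.12) and with the length trend removed (0.03). Epithelial genes had a median of 0.29 over 5 members, at the 73.9 percentile, or 98.1 with matching on GC content. The epithelial keratin gene Krt19 was at 1.85 and 3.84 FPKM and the E-cadherin gene Cdh1 at 2.09 and 3.11 FPKM, while the more abundant Krt18 (70.2 and 54.1 FPKM) and Elf3 (1.97 and 1.58 FPKM) were lower.

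Notch pathway genes were lower in part. Notch3 was at 4.42 and 0.918 FPKM in the shLuc and shTaz columns and its target gene Heyl at 1.86 and 0.415 FPKM, the 2-fold lower genes among 13 members, while Rbpj was at 8.04 and 16.7 FPKM. The median of -0.31 lay at the 0.450 percentile. It lay inside the range with a mean of at least 5 FPKM (7.59, over 7 members), with matching on GC content (4.18) and with both trends removed (21.2, median -0.09). With the GC trend removed it was 0.01, at the 42.5 percentile, so that the direction was not kept.

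Hypoxia and proliferation genes were higher by small amounts. Of 17 hypoxia genes none differed 2-fold, yet 13 lay above the median of all genes. Ero1l, an oxidase of the endoplasmic reticulum, was at 5.35 and 10.4 FPKM in the shLuc and shTaz columns, the kinase gene Pdk1 at 7.75 and 14.4 FPKM, Vegfa at 84.5 and 132 FPKM, and the glucose transporter gene Slc2a1 at 58.5 and 88.5 FPKM. The median was 0.47, at the 99.985 percentile, and it lay above the range of random lists in each of the 12 alternatives. Of 23 cell cycle genes none differed 2-fold and 16 lay above the median of all genes. Ccnb1, or cyclin B1, was at 4.71 and 9.71 FPKM and the checkpoint kinase gene Bub1 at 0.882 and 2.43 FPKM, while Aurka was lower at 19.7 and 11.8 FPKM. The median of 0.34 lay at the 99.2 percentile, but inside the range with matching on GC content (91.4) and with the GC trend removed (91.5).

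Of the immune cell lists fixed before the data were examined, the neutrophil and macrophage markers lay above the range of random lists, with members in both directions. Of 4 measured neutrophil markers, S100a8 was listed at 0 in the shLuc column and at 18.6 FPKM in the shTaz column, S100a9 was higher (above), Csf3r was at 3.93 and 7.10 FPKM, and the protease gene Mmp9 was lower at 125 and 45.0 FPKM. The median of 2.39 lay at the 99.995 percentile. Without S100a8 it was 0.72, at 97.3, and over all 9 listed markers with no filter it was 0.54, at 99.35, with Cxcr2, Mmp8 and Camp also lower. Macrophage markers had a median of 0.34 over 15 members, at the 99.8 percentile, or 97.2 after quantile normalization. The mannose receptor gene Mrc1 was at 12.3 and 20.7 FPKM and the integrin gene Itgam at 29.1 and 45.7 FPKM, whereas the complement gene C1qa was at 1868 and 1470 FPKM. All 8 listed NK and B cell markers were under a mean of 1 FPKM, and the list was not placed among random lists.

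Interferon-stimulated and antigen presentation genes lay inside the range of random lists. Of 19 interferon-stimulated genes, Usp18 was 2-fold higher (0.773 and 2.85 FPKM), while Isg15 was at 16.1 and 8.56 FPKM. The median of 0.04 lay at the 12.4 percentile, and it was below the median of all genes in every setting. Its sign turned with median-ratio scaling (-0.08), quantile normalization (-0.13) and removal of the length trend (-0.09), the GC trend (-0.14) or both (-0.16). In these settings the median of all genes was lower too, so the side of the list did not change. The list median was -0.54, at the 0.115 percentile, over the 8 genes with a mean of at least 5 FPKM. Of 14 antigen presentation genes 13 lay below the median of all genes and none differed 2-fold. The class II genes H2-Ab1 (998 and 600.5 FPKM) and H2-Eb1 (491 and 336 FPKM) differed most, and the median of -0.31 lay at the 17.6 percentile. Among 15 immediate early genes, Nr4a1 (12.8 and 3.78 FPKM) and the phosphatase gene Dusp1 (24.0 and 10.7 FPKM) were 2-fold lower. The list median was -0.04, at the 29.8 percentile, and it turned to 0.04 with quantile normalization, 0.02 with the GC trend removed and 0.10 with both trends removed.

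Of 6 measured skeletal muscle markers 4 were 2-fold higher in the shTaz column, with Acta1, the skeletal muscle actin gene, listed at 0 and at 14.9 FPKM, Tnnt3 at 1.61 and 8.004 FPKM, Mylpf at 0.706 and 5.05 FPKM and Ckm at 0.436 and 2.30 FPKM. The median of 1.49 lay at the 99.995 percentile. It was 0.38, at 82.1, over the 3 members with a mean of at least 5 FPKM, 0.75 over all 13 listed markers with no filter (99.985), and 2.201 with a pseudocount of 0.1. Endothelial markers had a median of -0.10 over 11 members, at the 10.8 percentile, with Plvap at 67.2 and 36.2 FPKM and Cldn5 at 18.2 and 10.3 FPKM. The endothelial list lay below the range with a mean of at least 5 FPKM (0.185), with the length trend removed (1.32) and, barely, with both trends removed (2.49975). The 3 skin keratinocyte markers had a median of 0.38 at the 62.3 percentile, with Sfn at 1.29 and 3.30 FPKM and Krt14 at 5.49 and 3.88 FPKM. The 3 adipocyte markers had a median of -0.55 and a mean of 0.12, at the 2.64 percentile. This list lay below the range with matching on GC content (0.190) or length (1.82), with the length trend (1.06), the GC trend (0.275) or both (0.205) removed, and barely with median-ratio scaling (2.48), protein-coding genes (2.48) and genes above 0 in both columns (2.18), but at 24.8 over all 7 listed markers with no filter. Lpl was at 10.99 and 6.18 FPKM and Fabp4 at 39.8 and 26.8 FPKM, against the higher Pparg. The 4 erythroid markers had a median of 0.34 at the 87.8 percentile, with Alas2 at 2.07 and 3.79 FPKM. The abundant hemoglobin gene Hba-a1 was lower, at 265 and 217 FPKM, and Hbb-b2 was nearly equal, at 17.3 and 17.7 FPKM. Hba-a2 (0.413 and 1.61 FPKM) is a near-identical copy of Hba-a1 and is uncertain. The erythroid list lay above the range with matching on GC content (98.5) and with the length trend (97.97), the GC trend (99.1) or both (99.3) removed. These settings covered only the 3 members with a transcript length. With both trends removed their median was 0.71, the value of Alas2. The shift can therefore not be put down to GC content or length alone.

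Of the 20 lists placed among random lists, 9 lay outside the range, 3 below and 6 above. With matching on GC content 8 lay outside, with matching on length 10, and with both trends removed 10.

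**Figure D3:**
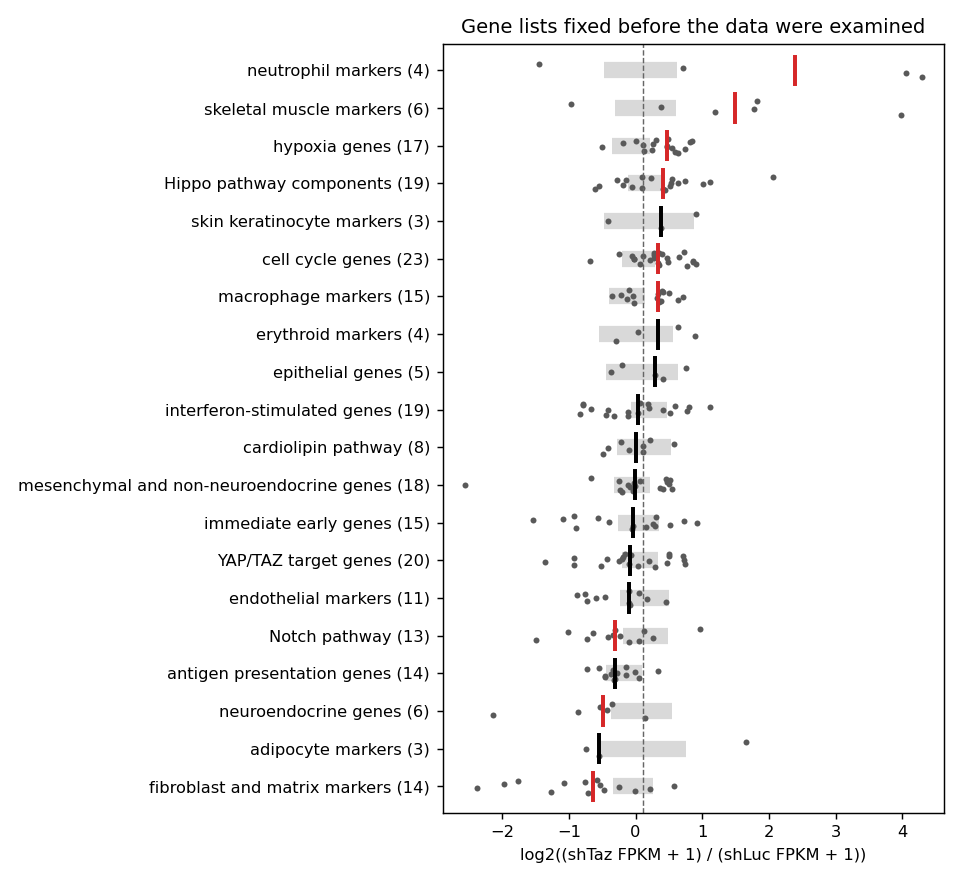
Each row is a gene list fixed before the data were examined, with its number of measured members in parentheses; points are members' log2 differences between the shTaz and shLuc columns (x axis), thick vertical bars are list medians, grey bands hold the middle 95% of medians of random lists matched on expression, and the dashed line is the median of all genes. Red bars mark the 9 lists outside their band, from the fibroblast and matrix markers (median -0.64) to the neutrophil markers (median 2.39).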

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

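Removal of the length or GC trend, matching on length or GC content, and the choice of genes above 0 or protein-coding were chosen after seeing the data. No paired analysis was possible because the table holds 1 column per group and no replicate numbers. For the same reason limma with and without trend or robust priors, the estimated correlation and leaving out each replicate were not run, and depth is unknown. Wwtr1 stayed lower in all 10 settings, from -1.09 to -0.60, and the number of lists outside the range stayed between 7 and 12. The choices of no filter, a mean of at least 5 FPKM, genes above 0 and protein-coding genes leave a gene's own difference unchanged. For single genes they are therefore no check. The number of genes 2-fold different was 1544 with a pseudocount of 0.1 (996 higher), since low values then count for more, and 434 with a mean of at least 5 FPKM (219 higher, 215 lower), where fewer genes were measured. It was 516 with the GC trend removed (166 higher) and 492 with both trends removed (184 higher). The higher genes numbered 294 after quantile normalization and 293 with the length trend removed. The YAP/TAZ target genes left the range of random lists with quantile normalization (2.40), the length trend removed (2.08) and matching on length (1.75). The neuroendocrine genes entered it with a mean of at least 5 FPKM (5.13), the GC trend removed (4.69) and matching on GC content (6.24). The replication-dependent histone genes went from the 2.40 percentile to 99.955 with the length trend, 99.965 with the GC trend and 99.995 with both removed. The cause of these last 3 changes was not tested. For the other 80 named genes, 56 of 758 values moved by over 1.5-fold, mostly with the pseudocount. The sign changed in 1 value, that of Yap1 with both trends removed (-0.01). The 758 values include those of the settings that only choose genes, which could not move.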

Other observations

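The lists in the next 2 paragraphs were chosen after their values were seen, so their percentiles describe the pattern and are no independent evidence for it. Elastic fibre and proteoglycan genes were lower in the shTaz column beyond the fixed matrix list. Of 18 members, 3 of which (Dcn, Fbln1 and Lum) are also in that list, 10 were 2-fold lower and none 2-fold higher. The 10 include Sfrp2, Dpt and Mgp, other secreted protein genes that are neither elastic fibre nor proteoglycan genes. Eln, or elastin, was at 184 and 31.6 FPKM in the shLuc and shTaz columns, the proteoglycan gene Bgn at 1388 and 294 FPKM, and the calcification inhibitor gene Mgp at 3956 and 985 FPKM. The median was -1.26, at the 0.0049995 percentile, although Fbln2, Ogn and Aspn were higher. Insulin-like growth factor binding genes and their CCN relatives were lower too, with 8 of 13 members 2-fold lower and a median of -1.10; Cyr61, Ctgf and Igfbp3 among them are also YAP/TAZ target genes. Igfbp2 was at 642 and 238 FPKM, Igfbp7 at 1299 and 606 FPKM and Wisp2 at 46.2 and 10.1 FPKM, while Htra1 was slightly higher. Mast cell genes were lower, with Tpsb2 at 14.2 and 0.409 FPKM, and Mcpt4 at 3.65 FPKM in the shLuc column and listed at 0 in the shTaz column. The 4 measured members had a median of -2.74, and all 9 listed members, with no filter, a median of -0.84. With a pseudocount of 0.1 the 4 members had a median of -4.47.

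All 10 measured neutrophil chemokine and inflammatory cytokine genes lay above the median of all genes, with a median of 0.70 at the 99.8 percentile, or 97.3 with a mean of at least 5 FPKM. Il1a was at 0.544 and 4.27 FPKM, Cxcl2 at 0.608 and 2.40 FPKM and Ptgs2 at 0.726 and 3.23 FPKM in the shLuc and shTaz columns, whereas Il1b differed less, at 22.4 and 27.6 FPKM. Hair follicle genes were higher in the shTaz column, where Krt71 (6.38 FPKM), Tchh (4.31 FPKM) and Krt27 (2.47 FPKM) stood against 0 in the shLuc column. Trps1 was present in both, at 2.41 and 4.57 FPKM in the shLuc and shTaz columns. The 5 measured members had a median of 2.11. With no filter the 13 listed members had a median of 0.53, and Krt85 was lower, while a pseudocount of 0.1 gave the 5 members a median of 4.68. Of 76 cytosolic ribosomal protein genes 72 lay below the median of all genes. Random lists matched on expression also lay below it, with a typical median of -0.27, so the count partly follows from abundance. The median of the ribosomal protein genes was -0.45, at the 0.0450 percentile, or 0.245 with matching on length. It lay inside the range after quantile normalization (50.4) and with the length trend removed (12.7). The 41 replication-dependent histone genes, with many near-identical copies, had a median of 0.00, at the 2.40 percentile. Its side of the median of all genes turned with the length trend, the GC trend or both removed, and also with no filter (0.33 over 53 genes, at 96.95). The list lay inside the range with a mean of at least 5 FPKM (4.72), median-ratio scaling (3.70), quantile normalization (7.45), genes above 0 in both columns (3.14) and matching on length (82.0) or GC content (79.0), so no direction is given for it.

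Of the tests in the next 3 paragraphs, those of the first were set down before their values were seen but after the trend across all genes was known, and those on fibroblast and muscle genes after the list results were seen.

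AT-rich transcripts were higher and GC-rich transcripts lower in the shTaz column, with a Spearman correlation of -0.56 across genes. Transcript length as the source is argued against, since within 10 groups of genes of like transcript length the median correlation was still -0.535277. A GC bias that differed between the libraries is a candidate explanation. It would act on genes whatever their function, and within 286 annotated gene classes of 50 to 400 genes the median correlation was -0.595508, with values below 0 in all 286. Such values follow largely from the trend across all genes, and the classes share genes. They cannot tell a GC bias from another cause that follows GC content. A biological difference between the groups that follows GC content stays open and untested, and with 1 column per group it has no replicate check.

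Fibroblast and matrix genes were lower in the shTaz column, and so were mast cell genes, with Tpsb2 at 14.2 and 0.409 FPKM and Tpsab1 at 17.3 and 0.895 FPKM in the shLuc and shTaz columns. Neither the GC trend nor the length trend accounts for the fibroblast list as the whole cause, since its median lay at the 0.0049995 percentile of random lists matched on GC content and also of those matched on length. Fewer host fibroblasts in the shTaz tumors may lower such genes, and so may a lower expression in the transplanted cells, and these cannot be told apart. The outcome set down for a loss of host cells was that all measured members lie below the median of all genes by about the same amount. Of 14 members, 2 (Col6a3 and Pdgfra) lay at or above it. The transplanted cells may express some of these genes too, so this count cannot decide the question. Without replicates it is also not known whether these 2 differ from the rest by more than the spread. An effect of the knockdown itself was not tested.

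Skeletal muscle genes were higher in the shTaz column, and so were hair follicle genes, with Krt71 and Tchh listed at 0 in the shLuc column and at 6.38 and 4.31 FPKM in the shTaz column. For the muscle list the GC and length trends are argued against as the whole cause, with the median at the 99.995 percentile of random lists under either matching. Muscle tissue taken along with the shTaz tumors may raise these genes, and so may expression in the tumor cells, and these cannot be told apart. Of the 13 listed markers 12 were higher, 10 of them above the median of all genes, but this count restates the pattern, and 7 of the 13 had a mean under 1 FPKM. The abundant markers were mixed, with Acta1 listed at 0 and at 14.9 FPKM, Tnni2 at 21.6 and 28.4 FPKM, and Tnnc2 lower, at 12.4 and 5.86 FPKM.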
